A study of Oryza sativa with 2 samples.

How the data were processed

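Total RNA from leaves of 4-week-old control and OsSGS3b mutant rice plants was hybridised to 2 two-colour Agilent arrays, 1 control and 1 mutant RNA on each, with the dyes exchanged between the arrays. Per the labels' protocols, cDNA was made from total RNA with an oligo(dT)-type primer and labelled with Cy3 or Cy5 nucleotides. Genotype and dye were taken from the labels of each channel. The arrays were extracted with Agilent Feature Extraction 10.5.1.1, per the submitters' processing notes and the file headers.

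Each deposited file holds 45151 spots. Per the file headers, the authors' software removed background and spatial trends, replaced low signals by surrogates and normalised the dyes within each array by linear scaling and lowess. The deposited ratio is the log10 of Cy5 over Cy3 processed signal, and on all 4406 and 6094 rice spots where both channels held a surrogate it is 0. The deposited p-value of each spot comes from the software's error model within 1 array, per the file headers. The deposited signals are intensity values on a linear scale: processed, background-subtracted, and median with local background. Because surrogates stand in for low signals, ratios of probes that are absent in 1 genotype depend on the surrogate. Within-array lowess removes any overall shift between genotypes, so changes are relative to the bulk of probes. The header of the array 2 file holds summary values that its spots do not give, so only the spot values were used.

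Log10 ratios were turned into log2 mutant over control. Control spots and plant control probes were left out, which gave 43144 rice spots, and 92 spots marked as saturated, non-uniform or population outliers on either array were dropped. Replicate spots of a probe were combined by their median on each array. Probes well above background for the mutant on both arrays or for the control on both arrays were kept, 32129 in all, of which 121 had replicate spots. No spot was marked saturated. The 153 negative control spots had background-subtracted means between -5.412 and -3.394 and SDs between 3.53 and 16.2 in the 4 channels, which sets the level below which ratios are not informative. The number of arrays, 2, limits precision.

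The comparison was fitted with limma 3.58.1 in R 4.3.3, using +1 where the mutant was Cy5 and -1 where it was Cy3 as the design, which leaves 1 residual degree of freedom per probe, and empirical Bayes moderation (prior 6.94 degrees of freedom). P-values were adjusted by the Benjamini-Hochberg method over the kept probes with a threshold of 0.05. Gene lists, 24 in all, were written as annotation patterns and loci, and were tested with camera at a preset inter-gene correlation of 0.01 and adjusted over the lists. An estimated correlation rests here on 1 residual degree of freedom, so it is poorly determined, and with it 0 of the 9 called lists held. The count of probes at least 2-fold on both arrays needs no variance estimate and is set against the count in opposite genotype directions. Genes are named by locus and description as the annotation in the files gives them. The table of reference gene names does not share these locus identifiers and was not used. Kept probes represent 21996 loci. The values of 1 member of the clock and flowering list are not reported here.

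The lists, tests, alternatives and the rule for named genes were set before the data were examined. The rule takes the SGS3 loci on chromosome 12, the 12 highest and 12 lowest genes by the smaller of their 2 absolute log2 ratios among those past the threshold (1 probe per gene, the brightest, annotations without a function left out), up to 4 members of each list by the same ranking, and the ARF loci. Other loci and groups were chosen after their values were seen, namely the photosynthesis loci Os02g0197600, Os08g0435900, Os11g0707000, Os12g0274700, Os01g0869800, Os09g0439500 and Os09g0296800, the other Rubisco small and large subunit loci, the count of chlorophyll a/b-binding probes and the photosynthesis list without plastocyanin-like proteins. The fit was tested on simulated data with the spread of these arrays: of 200 changed probes among 32129, 88.0% were called at a log2 change of 1 and 100.0% at 2, and 18 of 206 calls were false. With 24 simulated lists, the 1 shifted list was called and 0 others. The simulated probes were drawn independently and the list members at random. The simulation therefore could not show false calls of lists whose members move together.

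Alternatives were normexp background correction with an offset of 50 and loess, no background subtraction with loess, no lowess with a floor of 5, no filter, a stricter filter, a pseudocount of 32, scaling between arrays, other variance models, 4 separate channels, treat with a log2 threshold of 0.58, the error-model p under 0.01 on both arrays, fold thresholds of 1.5 and 3, 1 probe per gene, fry, camera on ranks, and each array alone. The photosynthesis list without plastocyanin-like proteins, also with 1 probe per gene or an estimated correlation, was added after the data were seen. Tables, permutations and plots used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.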

Results

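RNA from leaves of 4-week-old rice plants was compared between control plants and plants carrying a mutation in OsSGS3b. SGS3 proteins stabilise RNA that an RNA-dependent RNA polymerase copies into double strands, a step in the making of trans-acting small interfering RNAs (tasiRNAs). Each of 2 dual-dye arrays carried 1 control and 1 mutant RNA, and the labels call the pairs biological replicates. The mutant was labelled with Cy5 on array 1 and with Cy3 on array 2, so that a difference tied to a dye appears with opposite genotype directions on the 2 arrays. Of 42340 rice probes with an unflagged spot, 32129 probes from 21996 loci were well above background for at least 1 genotype on both arrays and were kept. The share of detected spots was similar: 78.2% of mutant and 74.4% of control spots were well above background on array 1, and 72.6% and 73.2% on array 2. Median background-subtracted signals differed, at 801.2 for the mutant and 277.8 for the control on array 1, and 383.1 and 579.5 on array 2. The Cy5 channel was the brighter on both arrays. After dye normalisation the medians were 415 and 413 on array 1 and 358 in both channels of array 2. Ratios below are log2 mutant over control, given as the mean ± SD of 2 arrays, and the number of arrays limits their precision.

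The question of the design is which transcripts differ between the mutant and the control leaf. The targeted family came first. The locus Os12g0197700, annotated as an XS zinc finger protein, the domain found in SGS3, had a mean signal of 12976 in the control and 1070 in the mutant. It fell by 3.60 ± 0.26 on the log2 scale, 12.2-fold, with values of -3.79 on array 1 and -3.42 on array 2 (adjusted p = 5.52e-07, limma). Its neighbour Os12g0197500, also an XS zinc finger locus, rose on each of its 3 probes, by 0.78 ± 0.08, 0.78 ± 0.32 and 0.61 ± 0.06 (adjusted p = 0.00188, 0.00376 and 0.00629). The non-coding locus between them, Os12g0197600, had a ratio of -0.16 ± 0.06 and did not pass (adjusted p = 0.376). Which locus carries the symbol OsSGS3b is not given in the sources used here, and Os12g0197700 was read as the targeted locus because it was the one that fell, so it is no independent check of the labels. Where the mutation lies relative to the probes is not given either, and whether a probe takes signal from both copies was not tested. In the whole list of SGS3 and XS-domain proteins, 5 of 11 probes rose, 2 fell and 4 did not pass, the same counts as when adjusted over the list alone. Its median was -0.03 and its mean -0.00, while the camera direction was up (adjusted p = 0.631).

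Over all kept probes the difference between the genotypes was wide. Nicotianamine synthase Os03g0307300, which makes a metal chelator, went from a signal of 7.94 to 2818, and the metal transporter annotated Nramp6, Os07g0258400, from 342 to 46540. In the other direction the disease resistance locus Os11g0684100 went from 2845 to 4.56 and the protein kinase locus Os02g0615800 from 39735 to 56.8. In total 8326 probes rose and 8566 fell at an adjusted p under 0.05 (limma), together 52.6% of those tested. At least 2-fold in the same direction on both arrays were 3333 probes that were higher and 2773 that were lower, against 0 probes that were 2-fold in opposite directions. The ratios of the 2 arrays correlated across probes with Pearson's r = 0.956 and Spearman's rho = 0.902, where probes are not independent replicates. Across probes the 2 mutant channels had a rank correlation of 0.998, but for 121 probes with replicate spots the median SD between arrays, 0.27, was above that between spots of 1 array, 0.08 and 0.09, and over all kept probes it was 0.14; the labels do not say what separated the replicates, so p-values measure only the spread between these arrays, which may be technical. Also, the summary block in the header of the array 2 file differs from its own spot values, for instance 216 against 364 for the median background-subtracted Cy3 signal, while in the array 1 file both are 262.

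**Figure D1:**
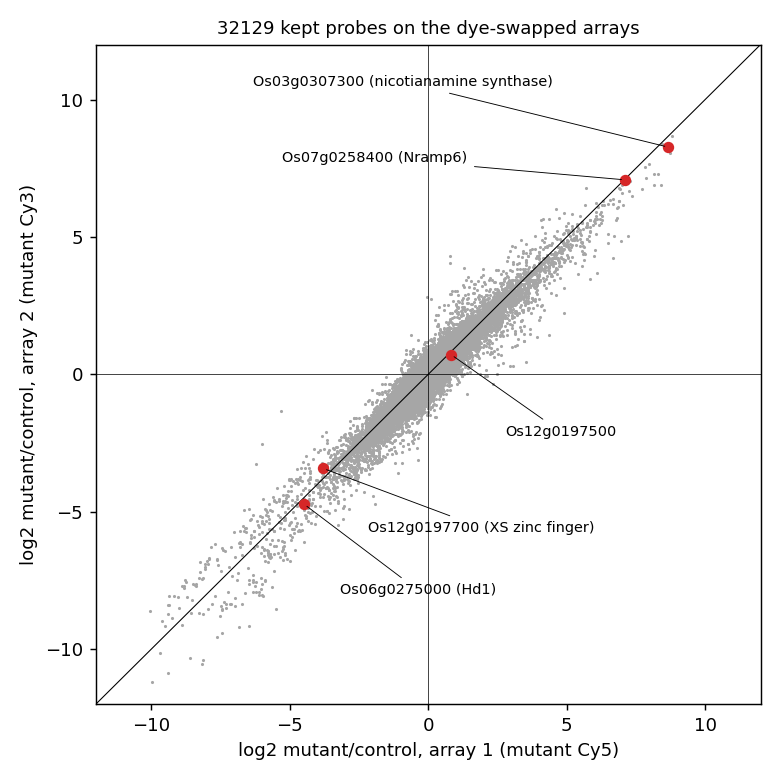
Log2 mutant over control of each of 32129 kept probes on array 1 (x axis) and array 2 (y axis), with the line of equal values. Points lie along the line (Pearson's r = 0.956), and the marked loci include Os12g0197700 at -3.79 and -3.42 and Hd1 (Os06g0275000) at -4.48 and -4.72.

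The 12 genes with a named function that were highest in the mutant spanned several families. After nicotianamine synthase Os03g0307300 (8.47 ± 0.28) came the lipase Os06g0156600 (7.69 ± 0.21), the glutathione transferase Os09g0367700 (7.52 ± 0.87), the fasciclin-domain locus Os08g0502400 (7.23 ± 0.68) and Nramp6 Os07g0258400 (7.09 ± 0.02). The other 7 were the DOMON-domain locus Os11g0678200, the glycosyltransferases Os01g0638000 and Os05g0527000, the bHLH factor Os08g0414500, the glycoside hydrolase Os10g0160100, the leucine-rich repeat locus Os02g0615400 and the chalcone synthase family locus Os02g0813600, with means between 6.23 and 6.59. The 12 lowest included the protein kinases Os02g0615800 (-9.45 ± 1.20) and Os06g0581500 (-8.90 ± 0.70), the receptor kinase Os07g0541400 (-9.32 ± 1.01), LRK14 Os01g0114300 (-8.75 ± 0.35), the disease resistance loci Os11g0684100 (-9.28 ± 0.45) and Os11g0639600 (-8.47 ± 0.28), the thaumatin-like Os12g0629700 (-8.37 ± 0.23) and the leucine-rich repeat locus Os06g0274300 (-8.72 ± 0.92). Of the 12 lowest, 5 lie next to another locus at least 8-fold lower and detected in the control only, namely Os01g0114300, Os02g0616800, Os06g0581500, Os11g0639600 and Os12g0629700. The remaining ones were the IN2-2 protein Os04g0338100, the ribosome-inactivating protein Os02g0616800, the TRANSPARENT TESTA 12 protein Os03g0571700 and the ATP-binding cassette protein Os10g0432200. For most of these 24 genes the lower genotype lay near background, where the software puts in a surrogate or a few signal units decide the ratio, so the size of the ratio is a rough one and its direction the firmer part.

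**Figure D2:**
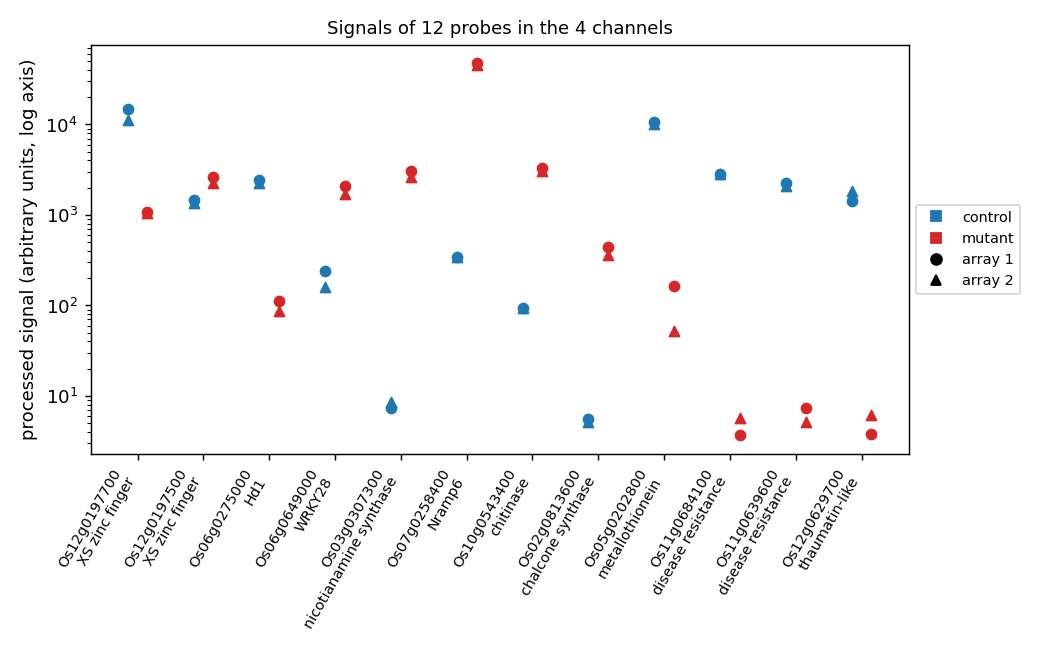
Processed signal (arbitrary units, log axis) of 12 probes in the control (blue) and mutant (red) channels of array 1 (circles) and array 2 (triangles). For Os12g0197700 the arrays gave 1080 and 1060 in the mutant against 14900 and 11300 in the control, while the mutant signals of the metallothionein Os05g0202800 lay further apart, at 164 and 52.1.

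Auxin response factor (ARF) loci of the type known as tasiRNA targets changed on a minority of probes. Of 8 probes of the 4 ARF loci in the list, 1 rose, 2 fell and 5 did not pass, also when adjusted over the list alone. Os01g0670800 rose by 0.82 ± 0.23 (adjusted p = 0.00208) on its brighter probe, while its dimmer probe had 0.40 ± 0.82 (adjusted p = 0.208). Os05g0515400 fell on both probes, with ratios of -0.59 ± 0.25 and -1.08 ± 0.05. Os01g0753500 had -0.32 ± 0.03 (adjusted p = 0.0831) and the brightest probe of Os05g0563400 had 0.16 ± 0.17 (adjusted p = 0.37). The list as a whole had a median of 0.17 but a mean of -0.03 and a camera direction of down (adjusted p = 0.988). Among 46 probes of the RNA silencing machinery, 5 rose, 12 fell and 29 did not pass, with a median of -0.09 (camera adjusted p = 0.306). Its clearest members were Os03g0800200, annotated Argonaute, at 2.91 ± 0.25, Os02g0169400, Argonaute 4, at -2.52 ± 0.08, Os02g0672200, a PAZ-domain Argonaute, at -0.98 ± 0.03, and a second Argonaute 4 locus, Os07g0471300, at 0.92 ± 0.07. The first pair was near background in 1 genotype. Of 86 auxin response probes, 29 rose, 25 fell and 32 did not pass (camera adjusted p = 0.569), among them the SAUR locus Os08g0452500 (3.57 ± 0.12), the GH3 homolog Os07g0592600 (3.05 ± 0.36) and the Aux/IAA locus Os12g0601400 (-3.55 ± 0.28).

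Probes of photosynthesis genes fell as a group. Of 216 probes from 80 loci, 152 fell, 41 rose and 23 did not pass, with a median of -1.24 (camera adjusted p = 1.01e-08). With an estimated correlation the adjusted p = 0.757, and with 1 probe per gene the median was -0.34 and the adjusted p = 0.23. The annotation pattern also took in 18 loci of plastocyanin-like domain proteins, a copper-binding domain not tied to the photosystems, mostly dim; without them, a step chosen after the values were seen, 193 probes had a median of -1.28 (camera adjusted p = 1.10e-12, adjusted p = 0.757 with an estimated correlation) and 1 probe per gene a median of -0.84 (adjusted p = 0.0104). Of 68 probes annotated as chlorophyll a/b-binding proteins, which harvest light, 66 fell, 1 rose and 1 did not pass. They come from only 12 loci, so many are repeats of the same transcript. The 20 probes of Os02g0197600 fell with a median of -3.14, while Os09g0439500 rose by 0.70 and Os09g0296800 had -0.09. The 9 probes of Lhca4, Os08g0435900, fell with a median of -2.46. All 11 probes of Rubisco activase Os11g0707000 fell (median -1.30). The list held members that went the other way. All 7 probes of the Rubisco small subunit locus Os12g0274700 rose (median 1.88), as did the 3 probes of PsbS, Os01g0869800 (median 2.26), and the 22 kDa photosystem II protein Os04g0690800 (5.81 ± 0.28). The small subunit loci Os12g0291100 (median 1.58), Os12g0291200 (1.81), Os12g0291400 (2.72) and Os12g0292400 (1.39) also rose, while Os11g0298400 (-0.24) did not pass. Among loci annotated as large subunit precursors, each with 1 probe, Os06g0598500 (2.23), Os10g0356000 (2.37) and Os05g0427800 (1.82) rose and Os01g0791600 (0.18) did not pass. No locus of the list annotated as a Rubisco subunit fell. Whether the probes of these loci read separate transcripts was not tested, so they may not be separate observations. Counted by locus on the brightest probe, 39 fell, 25 rose and 16 did not pass, and without the plastocyanin-like loci 37 fell, 15 rose and 10 did not pass.

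The list of clock and flowering loci was also lower as a group. Of 29 probes from 11 loci, 17 fell, 1 rose and 11 did not pass (median -0.49, camera adjusted p = 0.0013, adjusted p = 0.614 with an estimated correlation). Hd1, Os06g0275000, a photoperiod regulator of heading date, fell by 4.60 ± 0.16 from a signal of 2358 to 98.2. The response regulator loci Os09g0532400 and Os02g0618200, entered in the list as clock genes, had ratios of -1.82 ± 0.45 and -0.89 ± 0.06. With 1 probe per gene the list had a smaller median, -0.28, and a camera adjusted p = 0.23. The list does not speak for flowering loci in general. MADS-box loci lie outside it, and of 54 probes annotated MADS, 22 rose, 14 fell and 18 did not pass.

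Of 214 probes for NBS-LRR proteins, the intracellular receptors of pathogen effectors, 96 fell, 42 rose and 76 did not pass, with 40 at least 2-fold lower on both arrays and 15 at least 2-fold higher (median -0.29, camera adjusted p = 0.00712, adjusted p = 0.614 with an estimated correlation). Besides the loci above, Os11g0686500 (-7.31 ± 0.85) and Os11g0229500 (-6.88 ± 0.94) fell. Of the 214 probes, 12 were at least 8-fold lower and detected in the control only. The call was lost in a stricter filter that asks for detection in both genotypes (median -0.23, adjusted p = 0.0865) and without a filter (median -0.11, adjusted p = 0.134). In the list of kinases with receptor domains, 54 of 97 probes rose, 12 fell and 31 did not pass (median 0.55, camera adjusted p = 3.63e-04, adjusted p = 0.614 with an estimated correlation). The lectin-like receptor kinase Os07g0132500 rose by 3.82 ± 0.23 and the receptor-like kinase Os01g0784500 by 3.01 ± 0.08, while the nodulation receptor kinase locus Os07g0568100 had -3.06 ± 0.08. The list's annotation pattern does not take in the receptor kinase Os07g0541400 or LRK14 Os01g0114300, which are among the 12 lowest genes above.

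Several metabolic and stress groups were higher in the mutant. Terpene and phenylpropanoid enzymes rose on 50 of 92 probes, fell on 15 and did not pass on 27 (median 0.70, camera adjusted p = 3.49e-04, adjusted p = 0.614 with an estimated correlation). Examples were the chalcone synthase family loci Os02g0813600 (6.25 ± 0.14) and Os10g0472900 (5.55 ± 0.00), ent-kaurene oxidase Os06g0569900 (5.20 ± 0.31), which acts in gibberellin synthesis, and the terpene synthase Os02g0570400 (4.09 ± 0.05). The median of this list was smaller with 1 probe per gene (0.37, camera adjusted p = 0.0139) and without a filter (0.11, camera adjusted p = 0.0108). Of 227 peroxidase and glutathione transferase probes, 92 rose, 63 fell and 72 did not pass (median 0.22, camera adjusted p = 0.0237, adjusted p = 0.757 with an estimated correlation), led within the list by the peroxidases Os01g0378100 (5.81 ± 0.52) and Os01g0294700 (4.95 ± 0.09). Of these probes 15 were at least 8-fold higher and detected in the mutant only, and the call was lost in the stricter filter (median 0.18, adjusted p = 0.11), without a filter (median 0.04, adjusted p = 0.0574) and with 1 probe per gene (median 0.23, adjusted p = 0.0823). Jasmonate genes rose on 28 of 64 probes, fell on 11 and did not pass on 25 (median 0.29, camera adjusted p = 0.00367, adjusted p = 0.614 with an estimated correlation). Their members split: the ZIM-domain loci Os03g0180800 (3.70 ± 0.02) and Os03g0180900 (3.08 ± 0.08) rose, whereas the ZIM-domain locus Os02g0732400 (-4.02 ± 0.00) and the lipoxygenase Os02g0194700 (-2.79 ± 0.08) fell. With 1 probe per gene, 32 in all, this list had a median of 0.27 and a camera adjusted p = 0.0584.

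Ribosomal protein genes showed a small and broad rise. Of 519 probes, 272 rose, 20 fell and 227 did not pass, with only 29 at least 2-fold higher on both arrays (median 0.41, camera adjusted p = 1.60e-07, adjusted p = 0.614 with an estimated correlation). The 2 neighbouring loci Os05g0292600, annotated as a chloroplast ribosomal protein L14, and Os05g0292500, annotated as a ribosomal protein S11, rose by 2.91 ± 0.14 and 2.79 ± 0.15. Whether their probes read separate transcripts was not tested. Phosphate and metal homeostasis genes were lower as a group: 72 of 125 probes fell, 23 rose and 30 did not pass (median -0.51, camera adjusted p = 4.81e-04, adjusted p = 0.757 with an estimated correlation). With 1 probe per gene, 58 in all, this list had a median of -0.45 and a camera adjusted p = 0.066. The strongest members of the list pointed both ways, with the metallothionein Os05g0202800 at -6.81 ± 1.13 and a second nicotianamine synthase locus, Os03g0307200, at 6.03 ± 0.35.

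**Figure D3:**
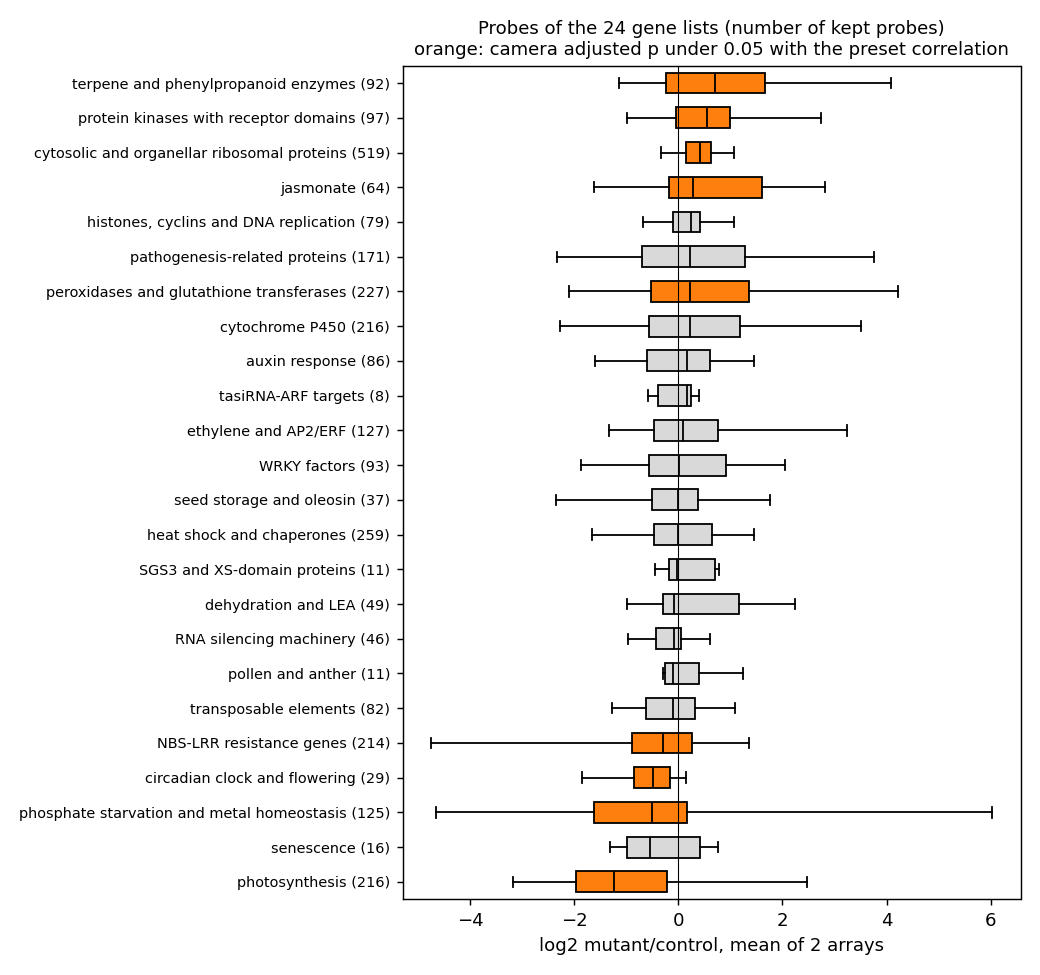
Log2 mutant over control (mean of 2 arrays) of the kept probes in each of 24 gene lists, with the number of probes in brackets. Boxes span the quartiles with the median as a line, whiskers run from the 5th to the 95th percentile, and orange marks the 9 lists with a camera adjusted p under 0.05 at the preset correlation; the photosynthesis median lies at -1.24 and the ribosomal one at 0.41.

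The other lists did not pass as groups at the main settings, though single members changed. The calls of 3 of them turned on the setting, as pathogenesis-related proteins passed in 4 alternatives (adjusted p = 0.0331 to 0.0424), cytochrome P450 genes in 3 (0.0331 to 0.042) and histones, cyclins and replication genes in 2 (0.0416 and 0.0477). Pathogenesis-related proteins had 77 of 171 probes that rose and 54 that fell (camera adjusted p = 0.0562), with the chitinase Os10g0543400 at 5.07 ± 0.07. Cytochrome P450 genes had 93 of 216 that rose and 67 that fell (0.0639), histones, cyclins and replication genes 20 of 79 that rose and 8 that fell (0.0714), and AP2/ERF genes 43 of 127 that rose and 34 that fell (0.362). Among WRKY factors 32 of 93 probes rose and 29 fell (0.631), for example WRKY28, Os06g0649000, at 3.28 ± 0.21. Heat shock and chaperone probes rose on 81 of 259 and fell on 69 (0.631). Dehydration and LEA probes rose on 14 of 49 and fell on 12, with a median of -0.09, a mean of 0.26 and a camera direction of up (0.631). Transposable element probes rose on 20 of 82 and fell on 26 (0.556), with the MuDR transposase Os07g0102900 at -8.16 ± 0.82 and the En/Spm-like locus Os07g0431000 at 6.11 ± 0.05. Senescence probes rose on 4 of 16 and fell on 8 (0.454). The seed and pollen lists did not move as groups: seed storage and oleosin probes rose on 9 of 37 and fell on 10 (camera adjusted p = 0.783), and pollen and anther probes rose on 4 of 11 and fell on 1, with a median of -0.11, a mean of 0.17 and a camera direction of up (camera adjusted p = 0.631). These lists rest on annotation text, which also took in lipid transfer domain and expansin domain proteins, so they are no check of the tissue. Adjusted over the list alone, no count of risen or fallen probes in any of the 24 lists moved by more than 7 probes.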

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

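The tests of second probes, neighbouring loci, lowess, matched lists and clock genes were set down before their results were seen; the test of the array 2 labels, that of several probes per gene with and without plastocyanin-like proteins, the split of neighbours by direction and the comparison of clock genes with the spread between their probes were chosen only after the result was seen.

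The locus Os06g0157700, annotated SP3D and entered in the clock and flowering list as the florigen gene Hd3a, was left out of the comparison by the filter on low signals. Its 2 probes gave signals of 28.9 and 30 in the mutant against 6.03 and 4.99 in the control on array 1, and mean log2 ratios of 1.99 and 2.17. It is listed because a signal above the control stands in probes the comparison did not use, and no explanation was tested.

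A set of 540 probes was at least 8-fold apart on both arrays and detected in 1 genotype only, 310 of them in the mutant and 230 in the control. NBS-LRR probes took 2.22% of the set against 0.666% of kept probes, all 12 lower in the mutant (Fisher's exact test, two-sided, adjusted p = 0.00355 over 24 lists), peroxidases and glutathione transferases 2.78% against 0.707%, all 15 higher (adjusted p = 1.91e-04), and ribosomal proteins 0.185% against 1.62% (adjusted p = 0.0226). The ribosomal value says little about these genes, since 516 of their 519 probes were detected in both genotypes and could not enter the set. Likewise 171 of 214 NBS-LRR and 196 of 227 peroxidase and glutathione transferase probes were detected in both, against 29567 of all 32129 kept probes. The background of the test was all kept probes. Its results for these lists may therefore reflect how often their probes were detected in both genotypes, rather than an excess of large changes. The test takes probes as independent, although the 540 come from 453 loci, so its p-values may be too low. For loci with a second probe, a base difference under single probes between the lines is argued against as the main cause. Of 128 second probes of the same loci with another sequence, 91.4% (95% exact interval 85.1 to 95.6) were at least 2-fold in the same direction. This was close to the 95.4% for 8-fold probes detected in both genotypes. Most of the 453 loci had no such second probe, so for them this explanation could not be tested. Chromosome segments that differ between the lines may be part of the pattern, as 49 pairs of neighbouring loci were both in the set, 5.29 times the mean of random draws (permutation p = 1.00e-04, one-sided, the smallest 10000 draws can give), against 1.72 times for loci at least 4-fold apart and detected in both genotypes. The ratio was 21.24 for loci detected in the control only (38 pairs) and 2.08 for those in the mutant only (6 pairs, permutation p = 0.0733, one-sided), and an effect of the mutation on expression of these loci stays open and untested, since the labels do not say whether the lines are otherwise alike. Neighbouring members of 1 gene family can form pairs too. Leaving out 3 pairs with the same description left 46 pairs, 4.97 times the mean of random draws. Alike wordings counted as different, as for the isoflavone reductase loci Os01g0106300 and Os01g0106400, so family pairs were not fully separated.

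The photosynthesis list was lower in the mutant over its 216 probes. Lowess acting on bright spots is argued against, since without lowess the list's median was -1.05 on array 1 and -2.02 on array 2. Whether bright spots dropped in general cannot be told from matched lists, since lowess had already centred the ratios at each signal level. Of 10000 random lists matched on mean signal, 0 had a median as low and the lowest was -0.13. The list thus lay below probes of like signal. Another hour of harvest stays open: the morning gene Os08g0157600 (-0.69) and the evening gene Os02g0618200 (-0.93) fell together, but the evening gene Os01g0182600 (-0.16) lay within the spread of its probes (SD 0.22), and Os09g0532400 (-1.82) fell where no probe of Os07g0695100 passed. Whether many probes of a few genes set the size of the shift stays open, since with 1 probe per gene the median was -0.34 over 80 loci but -0.84 over the 62 that are not plastocyanin-like domain proteins; 13 loci with at least 5 probes gave 109 of the 216 probes and 97 of those that fell. That the mutation lowers these transcripts stays open as a hypothesis that was not tested.

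The header of the array 2 file and its spots disagree. The header gives 2490 and 2238 spots with an error-model p under 0.01 with Cy5 higher and lower, and a median Cy3 spike-in signal of 86.8, where the spots give 6613, 6760 and 1233; for array 1 these quantities differ by at most 0.616%. Spots from another comparison than the label says are argued against, since the ratios of both arrays, oriented by the labels, correlated across kept probes at 0.956. Where the header came from stays open, and no biological explanation applies.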

How the results depend on the processing

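Alternatives other than the 1.5-fold and 3-fold thresholds left the number of concordant 2-fold probes (6106) within 1.5 times, and every normalisation kept the number of changed probes, mutant against control (16892), within 1.5 times. The count of changed probes was 7169 with treat at a log2 threshold of 0.58, 10524 with the error-model p in the files and 0 with no filter on probes (limma, 16502 at an unadjusted p under 0.05, lowest adjusted p = 0.055). Without a filter the prior had 0.62 degrees of freedom and 3932 probes had a ratio of exactly 0 on both arrays; the cause was not tested. There the agreement of the 2 arrays was r = 0.903, and Os12g0197700, read as the targeted gene OsSGS3b, had the same ratio of -3.60 without passing (limma adjusted p = 0.0554, against 3.15e-137 to 4.64e-06 in the other 5 refits). With 1 residual degree of freedom per probe, the lowest of these rests on the spread pooled over probes. It is no measure of certainty from 2 arrays, and the main fit gave a limma adjusted p = 5.52e-07. The 2-fold count became 10472 at 1.5-fold and 3347 at 3-fold, and on single arrays 7058 to 7669. Os12g0197700 ranged from -3.79 to -3.42 on single arrays. Gene lists with adjusted p under 0.05 numbered 9 with the preset correlation, 8 to 11 under the other normalisations, filters, pseudocount and ranks, 4 with 1 probe per gene, 4 with fry and 0 with an estimated correlation; beyond the low residual degrees of freedom the cause was not tested. The photosynthesis and ribosomal lists, lowest in p by camera, were among those that did not pass with fry (fry adjusted p = 0.171 and 0.0802). With plastocyanin-like proteins taken out of the photosynthesis list, alternatives chosen after the data were seen, the lists numbered 9, with 1 probe per gene 6 and with an estimated correlation 0. Of 119 other named probes, 0 reversed a call where they had a value, with 58 of them left under the stricter filter. Without a filter 113 lost the threshold, in the other 5 refits 530 of 534 values had the same direction and side of the threshold, and on single arrays, which give no test, 237 of 238 values had the same direction. The ratio within an array is already paired, and 4 separate channels with no replicate block gave 17520 changed probes with genotype alone and 16603 with genotype and dye. One array alone has no residual degrees of freedom, so changed probes and lists have no value there. Below the signal of negative controls, ratios carry no information.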

Other observations

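The loci in this part were chosen after their values were seen. Of 54 probes annotated MADS, 22 rose, 14 fell and 18 did not pass (median -0.04). All 5 kept probes of the MADS-box locus Os07g0108900, annotated MADS15, rose, from 1.74 ± 0.02 to 5.95 ± 0.47 (n = 2), and the MADS-box locus Os03g0752800 rose from a signal of 319 to 14605 on the probe with the largest ratio, 5.51 ± 0.47, and by 0.62 ± 0.55 on that with the smallest. A second locus annotated SP3D, Os01g0218500, rose by 4.07 ± 0.21 (limma adjusted p = 2.74e-07), and the MADS1 locus Os03g0215400 by 2.20 ± 0.44 to 3.04 ± 0.34 on its 3 probes, the last of them near background in the control. The MADS-box locus Os03g0122600 fell on 5 of 6 probes, with a ratio of -2.32 ± 0.19 on the lowest, and Os03g0186600 fell on all 3, for example with -2.02 ± 0.17. Of 27 probes annotated CONSTANS, 15 fell, 8 rose and 4 did not pass (median -0.94), among them Os02g0610500 (-2.74 ± 0.14) and Os02g0731700 (-2.13 ± 0.05), which fell, and Os02g0724000 (1.76 ± 0.04) and Os07g0667300 (1.32 ± 0.11), which rose. Some MADS-box genes act in the floral transition, but the leaves were taken at 4 weeks and no label gives the stage of flowering.

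Probes annotated as microRNA loci were mostly dim: 99 of 510 were kept, of which 68 fell, 9 rose and 22 did not pass, with a median of -0.68. Many of these probes, though not all, had lower ratios on array 2 than on array 1, for example an osa-miR399d probe at -0.52 on array 1 and -2.36 on array 2. Whether low signal adds to the count of fallen probes was not tested. All 3 kept probes of osa-miR398a fell, with ratios of -6.88 ± 0.72, -5.64 ± 0.01 and -4.73 ± 2.08. The kept probes of osa-miR398b had much smaller ratios, at -0.76 ± 0.44, -0.53 ± 0.54 and -0.36 ± 0.49. Several probes of the miR169 family fell, for example osa-miR169h (-2.83 ± 0.01) and osa-miR169g (-2.22 ± 0.04), as did osa-miR399i (-2.28 ± 0.08), whereas osa-miR159a rose by 1.81 ± 0.37 and 1.56 ± 0.03. The RNA was primed with an oligo(dT)-type primer, so these values are no measure of mature small RNAs.

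Runs of neighbouring loci detected in the control only stood out. On chromosome 6, Os06g0118600, Os06g0118700, Os06g0118800 and Os06g0119100 had ratios of -4.82, -6.81, -3.94 and -6.46, and on chromosome 7, Os07g0486100, Os07g0486400, Os07g0486500 and Os07g0487100 had -5.68, -7.54, -4.24 and -4.02. A second probe of Os07g0486500 was detected in both genotypes, at -0.51 ± 0.19. Their annotations include an aspartic peptidase, a RhoGAP protein and a glycosyltransferase. Among all 49 neighbouring pairs in that set, 44 had the same direction.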
